A study of Nasonia vitripennis with 79 samples.

How the data were processed

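The series holds bulk RNA-seq of heads and abdomens of the parasitoid wasp Nasonia vitripennis. In this species unfertilised eggs normally become haploid males and fertilised eggs become diploid females. In the WOM polyploid line, diploid males and triploid females also occur, after RNA interference against a gene of the sex determination pathway. That gene was not analysed here. Females carried 2 or 3 chromosome sets at generation F2 or F14, and males carried 1 or 2 sets at F3 or F15. All wasps were sampled 1 day after emergence. Each combination of sex, ploidy, generation and tissue was a group of 5 libraries, except F14 triploid female abdomens with 4, which gives 16 groups and 79 libraries. Males were always 1 generation later than females, so sex and generation number could not be separated fully. Per the submitters' processing notes, poly(A) RNA was made into libraries with a NEBNext Ultra kit, and reads were aligned with STAR 2.7.11a and quantified with RSEM 1.3.1. The genome build behind the alignment was not given in the sources used here.

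The authors deposited a table of expected counts from RSEM for 14621 genes and a table of TPM (transcript abundance scaled to the same sum in every library) from RSEM. The deposited TPM table held 14613 genes, and 8 genes were in the count table alone. TPM summed to between 999999.2 and 1000000.8 in every library. Of the expected counts, 17.8% were not whole numbers, and 123 genes had a count of 0 in every library. Neither table held summary lines such as unmapped reads. Expected counts were rounded to whole numbers before testing. Gene identifiers were matched to symbols of the RefSeq annotation of assembly Nvit_psr_1.1, and 14621 of 14621 matched. Of these, 829 had a symbol other than a LOC identifier, and genes are named by symbol. Gene order along the reference was used only for a test on blocks of neighbouring genes.

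Total expected counts per library ran from 12.6 M to 95.0 M. Intervals from counting alone are narrow at this depth, and the spread between libraries set the precision. The labels do not say whether replicate libraries came from separate cultures or from pools of animals, so p-values measure only the spread between these libraries, part of which may be technical.

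Differential expression was tested in R 4.3.3 with edgeR 4.0.16, using quasi-likelihood F tests with robust dispersions. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, and libraries were scaled by TMM. A one-way model over the 4 groups of one sex and tissue gave the ploidy, generation and ploidy-by-generation contrasts. A model over 8 groups of one tissue gave the sex contrasts, and one over 8 groups of one sex gave the tissue contrasts. Sex was compared at equal ploidy (diploid females against diploid males) and at the usual ploidies (diploid females against haploid males). Both sex comparisons used the same female libraries, so they are not independent. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in the contrast. Log2 fold changes are given ± SE, and levels are mean CPM (counts scaled to library size) with TMM scaling. Where one arm was near 0, levels are given in place of the fitted fold change.

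Gene lists were matched by symbol alone. Of 24 lists, 22 were written before the data were examined. The lists of serine proteases and of yellow and royal jelly-like genes were added after the gene table had been seen. A list was tested where at least 5 members passed the filter, which 11 lists did in at least 1 contrast. The tested lists were the nuclear respiratory chain, detoxification enzymes (cytochrome P450, glutathione S-transferase and carboxylesterase genes), cuticle proteins, chemoreceptors, neuronal receptors and synapse, neuropeptide and hormone genes, immunity, DNA replication and cell cycle, DNA damage response, and the 2 added lists. Their test was camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a contrast. The same test was run with an estimated correlation, and fry was run as well. Camera called 86 of 238 list and contrast pairs, of which 3 held with an estimated correlation. For the lists given here, median, mean and test had the same sign. For each list the number of members called over all genes is given, and for part of them also the number adjusted over the list alone.

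The genes named were chosen by a rule written before the data were examined. It took the 3 largest positive and the 3 largest negative log2 fold changes among called genes with a mean of at least 5 CPM in the higher arm and no overlap between the libraries of both arms, with at most 2 LOC identifiers in each direction. The condition on overlap was not applied to the ploidy-by-generation contrasts. It also took up to 4 tested members of each list with the smallest adjusted p, the sex determination genes Tra, Dsx and Fru in every sex and ploidy comparison, and up to 5 genes called the same way in both generations. The text names a part of these. A few further values, such as those of Tm2, were looked at after the results were seen.

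The design was tested on simulated data made from these libraries. At a 2-fold change edgeR recovered 44.8% of changed genes in F2 female heads, 55.2% in F3 male heads, 53.7% in F14 female abdomens and 52.2% in F3 male abdomens. Over 8 simulated comparisons, 2.72 to 6.47% of the edgeR calls were false, against 10.2 to 19.9% of the calls by DESeq2 1.42.0. The simulation changed 200 genes per comparison and otherwise gave every group the same mean and dispersion. Most real contrasts called far more genes. Common dispersions also differed between generations fitted together (0.137 at F3 and 0.0487 at F15 in male heads). These rates therefore need not hold for the real contrasts.

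Alternatives fixed before the data were examined were DESeq2 with its own size factors, edgeR with RLE scaling, no low-count filter, limma-trend on log2(TPM + 1), a fit to other libraries (only the compared groups, or all libraries of a tissue), omission of libraries whose names end in A or B, and omission of each library in turn. Alternatives added later were counts thinned to 12634506 per library, and fits without the libraries labelled F2 diploid female abdomen, without D31 and D32, without D86 and D87, or, for lists in F3 male heads, without D13. Without the libraries labelled F2 diploid female abdomen, the sex contrasts in abdomens compared F14 diploid females with F15 males alone. The tissue contrast in females then left out the F2 diploid heads as well. Other splits of the compared libraries were drawn with a fixed seed, with 100 splits for ploidy and generation, 50 for sex and 40 for tissue.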

Results

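The comparisons asked how gene expression in heads and abdomens of Nasonia vitripennis differed with an added chromosome set, between early and late generations of a polyploid line, and between the sexes. Across all 79 libraries and 12713 genes, the first component of log2 CPM held 39.5% of the variance and the second 31.8%. Heads of both sexes lay close together, and abdomens lay apart from them by sex. Depth differed between groups: F14 diploid female abdomens had 46 to 95 M counts, against 16.9 to 17.5 M in the F14 triploid abdomens beside them. No pair of libraries within a group looked like 1 library entered under 2 names: the lowest chi-square per degree of freedom over 156 pairs was 7.57.

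**Figure D1:**
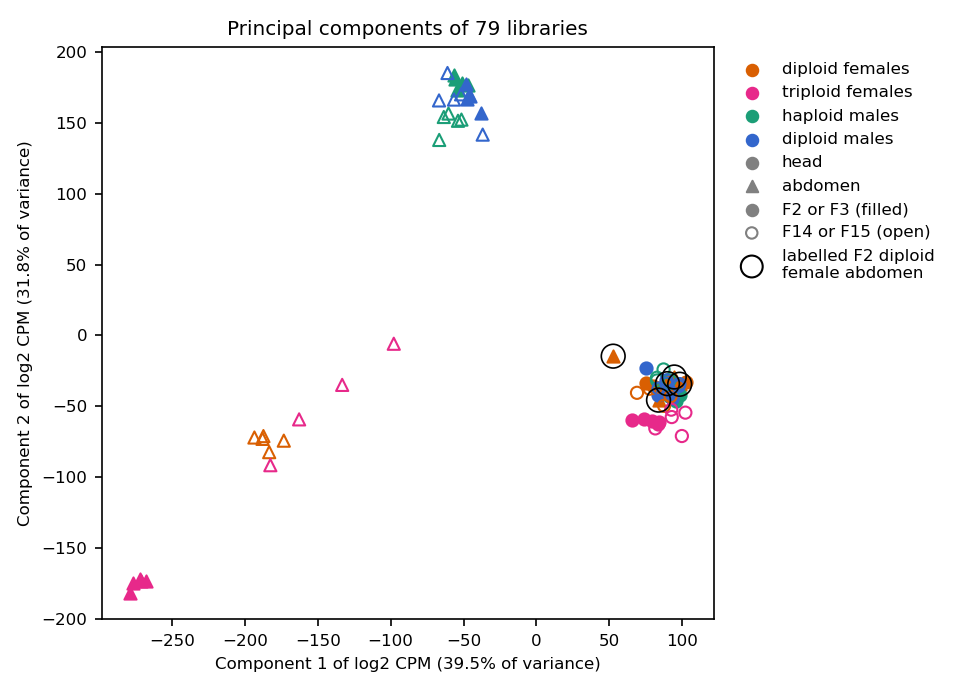
Scores of the 79 libraries on the first (x axis, 39.5% of variance) and second (y axis, 31.8%) principal components of log2 CPM, with 1 point per library. Colour marks sex and ploidy, shape tissue and filling generation, and the 5 libraries labelled F2 diploid female abdomen lie among the heads.

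Marker genes set the 5 libraries labelled F2 diploid female abdomen (D26 to D30) apart from every other abdomen group. The opsin Lop1, an eye photopigment, was at 2760 ± 1110 CPM (SD, n = 5) in them, between 1980 and 4680 CPM, whereas the means of the other abdomen groups ran from 0.0765 to 71.1 CPM. The germ plasm gene oskar was at 11.6 ± 15.7 CPM in them, against 635 ± 72.9 in F14 diploid female abdomens (n = 5) and 11.3 ± 12.9 in F2 diploid heads (n = 5). The synaptic gene Syt1 was between 587 and 889 CPM (mean 692) against 21.3 ± 4.34 in F14 diploid female abdomens. Over 1080 genes chosen as abdomen genes in the other libraries, these libraries differed from F2 diploid heads by a median log2 of 0.04 (quartiles −0.23 and 0.29) and from F14 diploid abdomens by −4.33. Only 122 of 12036 genes were called between them and F2 diploid heads, against 9088 between F14 diploid abdomens and heads. Comparisons that use these libraries are therefore given as values, and counts and some gene values are repeated without them where a contrast can be computed.

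**Figure D2:**
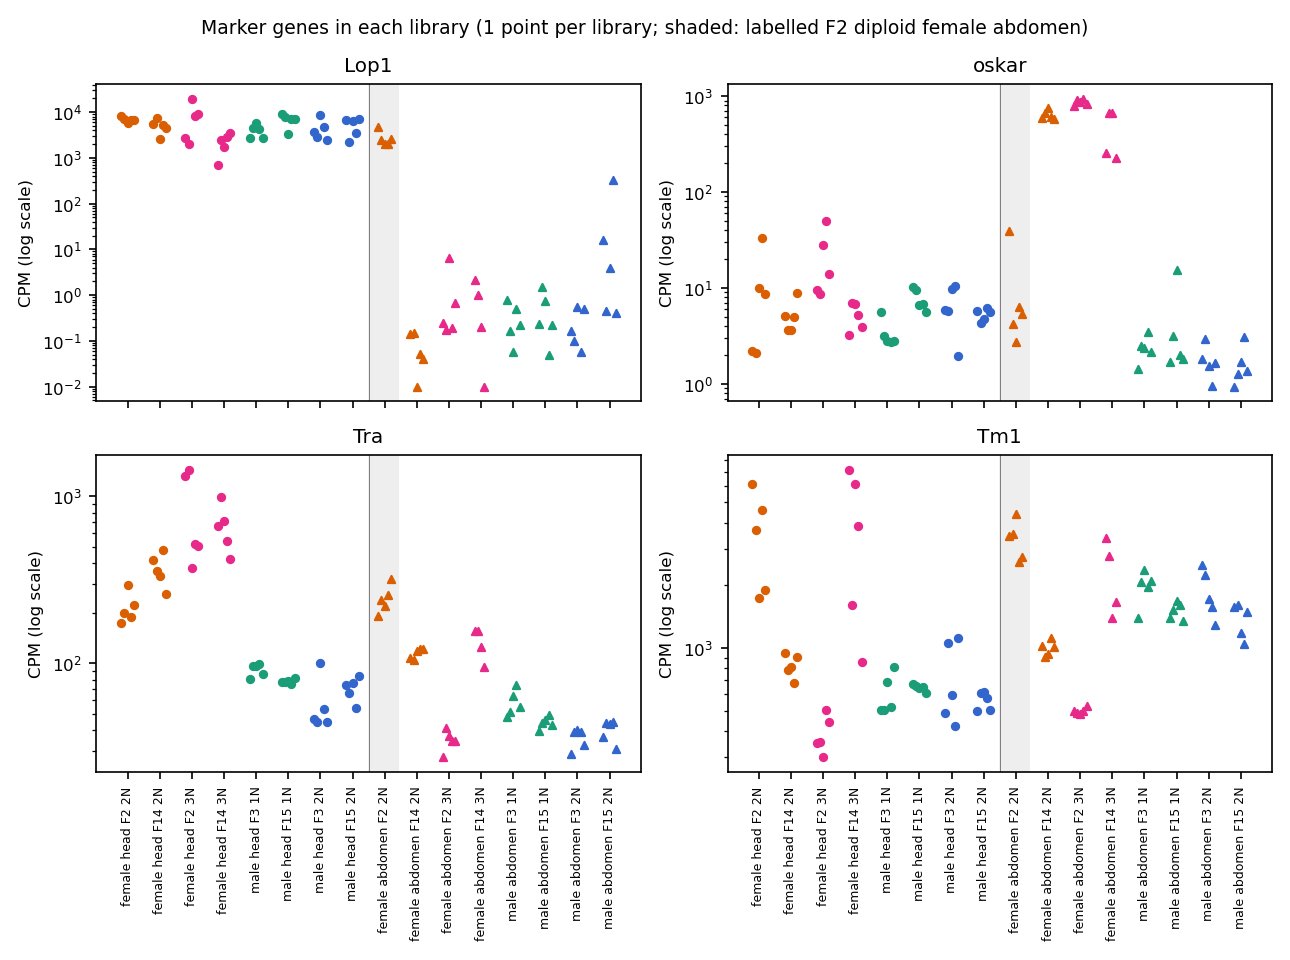
CPM (y axis, log scale, values at 0 drawn at the lowest tick) of the opsin Lop1, the germ plasm gene oskar, the splicing factor gene Tra and the muscle gene Tm1 in each of the 16 groups (x axis), with 1 point per library. Lop1 in the 5 libraries labelled F2 diploid female abdomen lies between 1980 and 4680 CPM, in the range of heads.

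In heads of F2 females, an added chromosome set went with higher Pdf, ACP and Tra and lower Tm1, Zasp66 and apd-3. Pdf, which encodes the peptide of circadian pacemaker neurons, was at 275 CPM in triploids and 46.1 in diploids, a log2 fold change of 2.58 ± 0.25 (adjusted p = 5.2e-07, n = 5 and 5). ACP, a neuropeptide related to adipokinetic hormone, rose by 2.14 ± 0.37 (adjusted p = 0.00015), or by 1.3 ± 0.28 (adjusted p = 0.0015) without D31 and D32. Tra, the splicing factor gene that directs female development, rose by 1.98 ± 0.35, from 211 to 831 CPM (adjusted p = 0.00015), and the ribosomal protein genes Rpl41 and Rpl39 rose by 2.72 ± 0.46 and 2.07 ± 0.37. The muscle genes Tm1 (tropomyosin) and Zasp66 fell to 387 and 58.8 CPM from 3520 and 406. Lower in triploids, too, were the apidermin cuticle gene apd-3, at 8.90 against 1160 CPM, the cuticle gene CPR37, at 0.337 against 21.6 CPM, the defensin Def1-2 (−4.04 ± 0.84), the acetylcholine receptor subunit gene nAChRb1 (−4.00 ± 0.51) and the cytochrome P450 gene CYP4AB14 (−3.52 ± 0.43), with adjusted p from 4.8e-06 to 0.00073. Of 63 nuclear respiratory chain genes 32 were called higher and 5 lower, or 33 and 5 adjusted over the list alone (camera adjusted p = 0.00281, adjusted p = 0.777 with an estimated correlation), with Ndufb7 at 1.11 ± 0.16 and Ndufb6 at 1.31 ± 0.21. Of 14 yellow and royal jelly-like genes, a list added later, 5 were lower (camera adjusted p = 0.0347, adjusted p = 0.777 with an estimated correlation), among them Mrjpl3 at −2.62 ± 0.42. Of 27 cuticle genes 1 was higher and 9 were lower, the same adjusted over the list alone (camera adjusted p = 0.0575), and of 15 neuronal genes 3 were higher and 6 lower. The sex determination genes Dsx (−0.30 ± 0.22, adjusted p = 0.29) and Fru (0.22 ± 0.21, adjusted p = 0.42) were not called, although Fru was called on TPM (0.77, adjusted p = 0.037). In all 4720 of 11127 genes were called, 2418 higher and 2302 lower in triploids, and 2584 of them changed at least 2-fold. The 5 triploid libraries were uneven: Tra was at 1329 and 1445 CPM in D31 and D32 and between 373 and 519.3 in the other three. Without that pair Tra was at 1.16 ± 0.24 (adjusted p = 0.0011), and 4689 genes were called. List counts moved more, with 5 cuticle genes lower and 1 higher, 9 neuronal genes lower and 1 higher, 36 respiratory chain genes higher and 3 lower, and 3 yellow and royal jelly-like genes lower and 1 higher.

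By F14 Tm1, Zasp66, apd-3, CPR37 and CPR48 differed in the other direction between triploid and diploid female heads. Tm1 was 2.25 ± 0.46 higher in triploids (3950 against 832 CPM, adjusted p = 0.0012, n = 5 and 5), and Zasp66 was 1.94 ± 0.52 higher (adjusted p = 0.0081, or 1.08 and 0.062 on TPM). The triploid libraries were uneven: Tm1 was at 7171, 6124 and 3831 CPM in D81, D83B and D84 but at 1618 in D82B and 858.3 in D85, against 683.8 to 951.3 in diploids. Zasp66 in D82B and D85 (134.8 and 107.6 CPM) lay within the range of diploids. The apidermin genes apd-1 and apd-3 were at 1120 and 2320 CPM in triploids, against 0.423 and 2.28 in diploids. CPR48 rose by 7.19 ± 0.88 (adjusted p = 1.4e-05), CPLCP2 by 6.53 ± 1.02 and CPR37 by 5.28 ± 0.90, and LOC100114648 was at 1390 against 0.784 CPM. Of 27 cuticle genes 11 were higher and 3 lower, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.107). The tropomyosin gene Tm2 was not called at F14 (−0.20 ± 0.14) or at F2 (0.06 ± 0.14). The defensin Def1-1 rose from a mean of 1.12 CPM (6.74 ± 1.39, adjusted p = 0.0013), CYP4AB9 rose by 4.16 ± 0.57 and CYP4AB14 by 2.89 ± 0.42. The serine protease gene SP128 fell to 0.392 from 9.57 CPM, CYP4G43, of a P450 family that makes cuticular hydrocarbons, fell by 3.84 on the log2 scale (SE 0.74, adjusted p = 0.00073), and the adipokinetic hormone receptor gene Akhr fell by 2.03 (SE 0.37). Of 63 respiratory chain genes 60 were called higher and 0 lower, with a median of 1.49; adjusted over the list alone the numbers were 61 and 0 (camera adjusted p = 5.74e-36, adjusted p = 0.295 with an estimated correlation). SdhB rose by 1.97 ± 0.19 (adjusted p = 2.2e-06), Atp5j by 2.24 ± 0.23 and Atp5d by 1.93 ± 0.21, and on TPM 56 of the 63 were higher and 1 lower. Of 148 chemoreceptor genes 6 were lower, 0 adjusted over the list alone (camera adjusted p = 0.00408, adjusted p = 0.737 with an estimated correlation). Tra (0.85 ± 0.34, adjusted p = 0.065), Dsx (−0.58 ± 0.22, adjusted p = 0.054), Fru (0.16 ± 0.21, adjusted p = 0.6) and Pdf (0.27 ± 0.23, adjusted p = 0.4) were not called. DESeq2 called Tra (adjusted p = 0.037) and Dsx (adjusted p = 0.043), as did the fit without D85 (adjusted p = 0.04 and 0.049). Tra was also called with the 2 F14 groups fitted alone (0.88 ± 0.24, adjusted p = 0.019). On TPM limma-trend called Dsx (−0.86, adjusted p = 0.026), and Pdf was at −0.30 and Fru at −0.18. Of 11127 genes 3302 were called, 1782 higher and 1520 lower, but limma-trend on TPM called 534 higher and 4009 lower, with the median of all genes moved by −0.461, so the split of directions held only with count scaling. The 10 most abundant genes took 6.48 to 14% of counts in the triploid heads and 3.64 to 4.91% in the diploid heads.

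Genes called in both generations of female heads were shared more often than independent lists would be, although Tm1, Zasp66, apd-3, CPR37 and CPR48 changed direction. Of the genes higher in triploids, 821 were called at both F2 and F14, against 387 expected (2.12 times, p = 6.3e-142 by a one-sided Fisher's exact test, which treats genes as independent), and 650 were lower at both, against 314 expected. Opposite calls numbered 93 and 266, against 330 and 369 expected. ACP was higher in both generations (2.05 ± 0.37 at F14), and Mrjpl3 (−2.89 ± 0.42 at F14), nAChRb1 (−1.46 ± 0.46, adjusted p = 0.055 without D83B) and the transcription factor gene hairy (−1.95 ± 0.42 at F2 and −2.57 ± 0.44 at F14) were lower in both. Across all genes, which are not independent replicates, the fold changes of both generations had r = 0.158 and rho = 0.287, and 62.6% of genes had the same sign.

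The ploidy-by-generation contrast in female heads tested those differences directly, as the triploid effect at F14 minus that at F2. Positive values included CPR37 (11.24 ± 1.32, adjusted p = 1.4e-05, n = 5 in each of 4 groups), CPR48 (9.33 ± 1.10) and apd-3 (17 ± 1.83), with CYP4AB14 at 6.41 ± 0.60, Def1-2 at 6.14 ± 1.14, Tm1 at 5.43 ± 0.66 and Zasp66 at 4.73 ± 0.74. The ATP synthase gene Atp5b was at 3.39 ± 0.46 and nAChRa10 at 2.21 ± 0.32. Negative values came from Pdf (−2.30 ± 0.34, adjusted p = 9.5e-05), Rpl41 (−3.04 ± 0.63) and SP128 (−5.27 ± 1.02). The other tropomyosin gene, Tm2, was not called (−0.25 ± 0.20, adjusted p = 0.38). Of 27 cuticle genes 13 were positive and 0 negative, or 13 and 1 adjusted over the list alone (camera adjusted p = 0.00305, adjusted p = 0.572 with an estimated correlation). Of the respiratory chain genes 35 were positive and 1 negative, or 41 and 1 adjusted over the list alone (camera adjusted p = 1.45e-14, adjusted p = 0.559 with an estimated correlation). Of 15 neuronal genes 5 were positive and 0 negative, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.00482, adjusted p = 0.559 with an estimated correlation). The contrast called 2705 genes, 1434 positive and 1271 negative. On TPM 19.1% of calls were positive in place of 53%, with the median of all genes moved by −0.401.

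Averaged over ploidy, several cytochrome P450 genes were lower in female heads at F14 than at F2. CYP6AQ4 fell by 1.99 on the log2 scale (SE 0.27, adjusted p = 0.00034, n = 10 and 10), CYP4AB9 fell by 2.35 (SE 0.37), CYP9P3 by 1.39 (SE 0.25) and CPR48 by 3.31 (SE 0.52). The values of CYP4AB9 and CPR48 average unlike changes: their ploidy-by-generation values were 5.96 ± 0.77 and 9.33 ± 1.10, over 2 times the average, so the fall was not shared by triploids. Srf, which encodes a transcription factor of the cytoskeleton and muscle, rose by 0.78 ± 0.13 (33.3 against 18.9 CPM, adjusted p = 0.0012). Of 64 detoxification genes 23 were lower and 0 higher, or 34 and 0 adjusted over the list alone (camera adjusted p = 2.16e-10, adjusted p = 0.225 with an estimated correlation). Of 35 serine protease genes, a list added later, 7 were lower and 1 higher, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.00753, adjusted p = 0.225 with an estimated correlation), among them SP43 (−2.66 ± 0.48). Of 11127 genes 1177 were called, 452 higher and 725 lower. This count moved with the libraries used: 758 without D94, 2740 without D31 and D32, and 1926 when male heads were added to the fit. On TPM 60.2% of calls were higher in place of 38.4%, with the median of all genes moved by 0.124.

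In F3 male heads, some odorant receptor, protease and cytochrome P450 genes differed between diploids and haploids. The odorant receptor gene Or140 rose by 2.54 ± 0.37 (8.41 against 1.44 CPM, adjusted p = 0.00028, n = 5 and 5), the serine protease gene SP137 by 2.96 ± 0.50 (adjusted p = 0.00094) and the glutathione S-transferase gene GstS5 by 2.02 ± 0.41 (175 against 43.0 CPM). The chaperonin subunit genes Cctgamma and Cct7 rose by 0.85 ± 0.12 and 0.58 ± 0.14, CPR35 by 1.37 ± 0.25 and Mrjpl3 by 1.58 ± 0.36. CYP6AQ4 fell by 2.08 (SE 0.28, 80.6 against 339 CPM, adjusted p = 0.00015), CYP6CK11 by 1.34 (SE 0.26), CYP6CK6 to 1.04 from 6.16 CPM, and Akhr by 1.05 (SE 0.18). Tra fell by 0.67 (SE 0.18, 62.6 against 99.8 CPM, adjusted p = 0.017), while Dsx (−0.10 ± 0.11, adjusted p = 0.51) and Fru (−0.07 ± 0.26, adjusted p = 0.86) were not called. Pdf was 0.86 ± 0.26 higher (176 against 97 CPM, adjusted p = 0.03), a call lost without any of D1, D1A, D4, D5 or D13, with adjusted p from 0.05 to 0.089. Of 26 cuticle genes 8 were higher and 1 lower, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.0144, adjusted p = 0.777 with an estimated correlation). Camera also called the respiratory chain (adjusted p = 0.0144) with 1 of 64 genes higher, 0 adjusted over the list alone, a median of 0.26 (−0.01 on TPM) and adjusted p = 0.777 with an estimated correlation, and that call was lost without D13 (adjusted p = 0.783), as was the cuticle call (adjusted p = 0.295, with 5 higher and 1 lower). Of 65 detoxification genes 21 were lower and 4 higher without D13 (camera adjusted p = 0.0302, adjusted p = 0.779 with an estimated correlation). The edgeR fit called 1780 of 11010 genes, 1086 higher and 694 lower, and 1053 without D5, 1155 without D1A and 1168 without D4. With the 2 F3 groups fitted alone it called 378 genes, with 2368 at an unadjusted p under 0.05, and Tra (adjusted p = 0.14), Mrjpl3 (adjusted p = 0.06), GstS5 (adjusted p = 0.059) and Cct7 (adjusted p = 0.11) were not among them. On TPM the median of all genes moved by −0.166.

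In F15 male heads the number of genes called between ploidies depended on the fit, with 12 beside the F3 groups and 128 with the 2 F15 groups fitted alone (39 higher and 89 lower). LOC100119124 fell by 1.82 (SE 0.27, adjusted p = 0.0078, n = 5 and 5) and LOC103317823 by 1.77 (SE 0.29, adjusted p = 0.013), while LOC100120889 rose by 1.90 ± 0.35 and LOC100678651 by 0.83 ± 0.15. All 4 calls were lost without D115 (adjusted p from 0.051 to 0.09), the calls of LOC100120889 and LOC100678651 also without D101, D104, D105, D111 or D113 (adjusted p from 0.058 to 0.11). LOC100120889 was also lost without D102, D112 or D114 (0.051 to 0.12), LOC100678651 without D103 (0.06), and LOC103317823 without D105, D111, D113 or D114 (0.051 to 0.069). Tra (−0.15 ± 0.18, adjusted p = 0.95), Dsx (−0.19 ± 0.11, adjusted p = 0.66) and Fru (−0.07 ± 0.26, adjusted p = 1) were not called. Of the respiratory chain and neuronal genes 0 were called, although camera called the neuronal list (adjusted p = 0.0193, adjusted p = 0.49 with an estimated correlation). The 12 genes were 2 higher and 10 lower, with 1001 at an unadjusted p under 0.05, 53 called higher and 53 lower by DESeq2, and 12 by limma-trend on TPM. Single libraries moved the count of 12 to between 1 without D115 and 22 without D112. It was 5 without D101, 7 without D102 or D104, 4 without D105 or D111, 3 without D113 and 5 without D114.

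The interaction in male heads gave positive values (less loss or more gain in diploids at F15 than at F3) for CYP6AQ4 (2.18 ± 0.39, adjusted p = 0.0056, n = 5 in each of 4 groups) and the transcription factor gene Creb (0.92 ± 0.16, adjusted p = 0.0043, but 0.063 on TPM). CPR35 (−2.26 ± 0.34), Mrjpl3 (−2.68 ± 0.50), Or140 (−2.37 ± 0.51) and Cctgamma (−1.03 ± 0.17) were negative. It called 393 genes, 143 positive and 250 negative, with 2421 at an unadjusted p under 0.05. The count was 896 by DESeq2, 135 with female heads added to the fit, 865 without D13 and between 225 and 259 without D101, D1A, D4, D5, D102, D104, D113 or D114. On TPM it was 216, with the median of all genes moved by 0.231. Between generations 0 genes were called higher in diploids at both F3 and F15, and 3 were lower at both, against 0.63 expected (one-sided Fisher's exact p = 0.021). DESeq2 gave 16 lower at both against 4.82 expected (one-sided Fisher's exact p = 1.1e-05), and without a low-count filter 2 were shared against 0.409 expected (p = 0.06).

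Between generations, detoxification genes were more often higher and respiratory chain genes more often lower in male heads at F15 than at F3. At F15 CYP6AQ4 was at 745 CPM against 210 at F3 (2.17 ± 0.20, adjusted p = 9.1e-07, n = 10 and 10), CYP6CK7 rose by 1.5 ± 0.21 and CYP6AQ5 by 1.37 ± 0.17. Of 65 detoxification genes 27 were higher and 4 lower, or 34 and 7 adjusted over the list alone (camera adjusted p = 3.4e-08, adjusted p = 0.729 with an estimated correlation), whereas that list fell in female heads; the difference between the sexes was not tested. Def1-2 rose by 1.91 ± 0.43 and the cytochrome oxidase assembly gene Cox15 by 0.61 ± 0.09. The cuticle genes CPR48 and CPLCP2 fell to 433 and 2.64 CPM from 10500 and 18.8, and CPR1 fell by 2.50 (SE 0.40). Of 64 respiratory chain genes 32 were lower and 1 higher, or 38 and 1 adjusted over the list alone (camera adjusted p = 9.75e-10, adjusted p = 0.729 with an estimated correlation), with Atp5o at −0.97 ± 0.18 and Atp5g2 at −0.76 ± 0.16. The test called 2621 genes, 1313 higher and 1308 lower. On TPM 70.1% of calls were higher in place of 50.1%, with the median of all genes moved by 0.13.

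In heads of both sex comparisons, the sex determination genes and several chemosensory and P450 genes differed. Tra was at 304 CPM in diploid females and 67.2 in diploid males (2.13 ± 0.20, adjusted p = 6.7e-10, n = 10 and 10), Dsx rose by 1.02 ± 0.13 and Fru by 0.63 ± 0.17 (adjusted p = 0.0074). Against haploid males Tra was 1.74 ± 0.20 higher, Dsx 0.89 ± 0.13 and Fru 0.57 ± 0.17. CYP4AB14 was lower in females by both comparisons, at 45.8 CPM against 835 in diploid males (−5.34 ± 0.26, adjusted p = 8.2e-18) and 860 in haploid males (−5.45 ± 0.27). CYP6CK8 was at 0.707 against 45.3 CPM in diploid males, LOC100122102 at 3600 against 1.15, and the carboxylesterase gene CCE-A4 at 5.09 against 0.465. Against diploid males Or296 was at −2.10 ± 0.35 and ACP at −1.88 ± 0.32. Pdf was lower than in diploid males (−0.87 ± 0.18, 83.9 against 142 CPM) but was not called against haploid males (−0.25 ± 0.18, adjusted p = 0.36). Of 166 chemoreceptor genes 37 were higher and 5 lower in females than in diploid males, the same adjusted over the list alone (camera adjusted p = 2.79e-07, adjusted p = 0.764 with an estimated correlation), and 69 and 5 against haploid males, or 91 and 5 adjusted over the list alone (camera adjusted p = 2.58e-12, adjusted p = 0.576 with an estimated correlation). Of 8 immunity genes 5 were higher in both comparisons (camera adjusted p = 0.0151 and 0.0148, adjusted p = 0.475 and 0.341 with an estimated correlation). The equal-ploidy comparison called 2838 of 11579 genes, 1251 higher and 1587 lower in females, and the comparison with haploid males called 2446, 1222 higher and 1224 lower. With only the 4 compared groups fitted, the latter called 4756.

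In female abdomens at F14, several cuticle and detoxification genes were higher in triploids than in diploids. CPR19 was at 2210 CPM in triploids (n = 4) and 226 in diploids (n = 5), a log2 fold change of 3.28 ± 0.31 (adjusted p = 9.2e-07), and CPR18 and CPR22 were at 51.7 and 31 CPM against 1.72 and 0.515. CYP4AB9 was at 149 against 1.32 CPM (6.83 ± 0.65, adjusted p = 1.2e-06), and the glutathione S-transferase genes GstT2 and GST-mic1 rose by 1.27 ± 0.12 and 1.10 ± 0.11. Tm1 rose by 1.41 ± 0.21, Zasp66 by 2.44 ± 0.37, Syt1 by 1.79 ± 0.27 and Akhr by 1.87 ± 0.26, while CPR35 fell by 2.65 (SE 0.39). Tm2 was not called (−0.30 ± 0.15, adjusted p = 0.135). Dsx rose by 1.53 ± 0.28 (501 against 173 CPM, adjusted p = 0.00037). The libraries D86 and D87 stood apart, with Tm1 at 3374 and 2755 CPM against 1395 and 1670 in D89 and D90A, and Dsx at 618.8 and 671.2 against 290 and 191.5. Genes chosen as head genes were also higher in that pair, at 2.49 and 2.11 against 0.66 and 0.98 (log2). Without the pair Tm1 was at 0.82 ± 0.16, Zasp66 at 1.68 ± 0.36, Syt1 at 0.91 ± 0.18, Dsx at 0.64 ± 0.20 (adjusted p = 0.026), CPR19 at 3.53 ± 0.32 and CYP4AB9 at 6.04 ± 0.62. Tra was 0.42 ± 0.16 higher (adjusted p = 0.048), a call lost without any of D86, D87, D96, D97, D98 or D100 (adjusted p from 0.057 to 0.16). Fru was not called (−0.45 ± 0.20, adjusted p = 0.073), except without D90A (−0.57, adjusted p = 0.035). The germline genes oskar (−0.29 ± 0.56, adjusted p = 0.7) and nanos (−1.50 ± 0.62, adjusted p = 0.06) were not called. The status of nanos depended on the fit: it was called without D90A (−2.24, adjusted p = 0.0079) and on TPM (−2.11). It was also called with thinned counts (adjusted p = 0.035), with the 2 groups fitted alone (adjusted p = 0.028) and without the libraries labelled F2 diploid female abdomen (−1.46 ± 0.37, adjusted p = 0.008). Without D86 and D87 nanos was at −0.94 ± 0.67. Of 69 detoxification genes 32 were higher and 0 lower, the same adjusted over the list alone (camera adjusted p = 3.86e-06, adjusted p = 0.202 with an estimated correlation). Of 27 cuticle genes 16 were higher and 1 lower, or 17 and 1 adjusted over the list alone (camera adjusted p = 0.000224, adjusted p = 0.202 with an estimated correlation). Of 63 respiratory chain genes 48 were higher and 0 lower, or 51 and 0 adjusted over the list alone (camera adjusted p = 3.88e-13, adjusted p = 0.441 with an estimated correlation), led by Uqcr11 (2.28 ± 0.27) and Atp5i (1.85 ± 0.23), and on TPM 36 were higher and 1 lower. Without D86 and D87, which leaves 2 triploid libraries, the respiratory chain had 23 of 63 genes higher and 0 lower with a median of 0.32, detoxification 24 of 71 higher and 1 lower, and cuticle 12 of 30 higher and 1 lower. Of 8 immunity genes 6 were higher, the same adjusted over the list alone (camera adjusted p = 0.041, adjusted p = 0.441 with an estimated correlation). Of 10 DNA damage response genes 3 were lower, 0 adjusted over the list alone. In all 4581 of 11454 genes were called, 2586 higher and 1995 lower, and 4057 without the libraries labelled F2 diploid female abdomen in the fit. Without D86 and D87 it was 2776, 1536 higher and 1240 lower. On TPM 36.8% of calls were higher in place of 56.5%, with the median of all genes moved by −0.188.

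For F2 female abdomens the comparison set triploid abdomens against the libraries labelled F2 diploid female abdomen, whose marker levels were those of heads. Germline and cell cycle genes were higher, with cycB at 1780 against 3.05 CPM, Cdk1 at 465 against 1.84, oskar at 978 against 11.4 and nanos at 81.6 against 0.698 (n = 5 and 5). Syt1 (4.23 against 687 CPM), Zasp66 (3.07 against 468) and Lop1 (1.73 against 2730) were lower. Tra (38.8 against 245 CPM, −2.66 ± 0.16) and Dsx (12 against 327 CPM, −4.77 ± 0.30) were lower as well, as was Fru (−2.28 ± 0.19). All 8 tested cell cycle genes and all 10 DNA damage response genes were higher, and of 63 respiratory chain genes 51 were lower and 2 higher. The test called 10198 of 11454 genes, 4940 higher and 5258 lower, and the interaction with generation, which uses the same libraries, called 9807, 5002 positive and 4805 negative, with cycB at −9.22 ± 1.19, Cdk1 at −8.45 ± 0.77 and nanos at −8.41 ± 0.99. DESeq2 moved the median of all genes by −0.731 in the F2 comparison and by 1.116 in the interaction, RLE scaling by −0.45 and 0.514, and TPM by −0.149 in the F2 comparison. Neither contrast can be computed without those libraries.

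Between F2 and F14, several cuticle and P450 genes rose in female abdomens. CPR19 rose by 3.11 ± 0.21 (1220 against 230 CPM, adjusted p = 3.5e-09, n = 9 and 10), CYP4G44 by 3.75 ± 0.32, CYP4AB12 by 3.03 ± 0.27, the serine protease gene SP142 by 3.75 ± 0.50 and Dsx by 2.23 ± 0.20, while Mrjpl3 and kinesin-2B fell by 0.97 (SE 0.10) and 0.99 (SE 0.11). In triploids alone, which leaves out the libraries labelled F2 diploid female abdomen, CPR19 rose by 7.21 ± 0.33, CYP4G44 by 5.80 ± 0.43, CYP4AB12 by 5.40 ± 0.37, SP142 by 5.94 ± 0.84 and Dsx by 5.40 ± 0.33, and Mrjpl3 and kinesin-2B were at −0.85 ± 0.13 and −0.83 ± 0.17. The F2 triploid abdomens differed from all F14 female abdomens in markers of several tissues as well, with Syt1 between 2.97 and 4.3 CPM against 18.36 to 101.5. Zasp66 was between 1.66 and 5.89 against 38.92 to 373.2, and cycB between 1490 and 1710 against 59.67 to 899.4. Their head genes lay between −2.29 and −1.79 against 0.56 to 2.49 (log2). Whether the shares of tissues in the samples differed was not tested, so the values in triploids alone rest on this point too. Of the tested chemoreceptor genes 7 were higher and 21 lower, or 4 and 12 adjusted over the list alone (camera adjusted p = 7.57e-21, adjusted p = 0.0354 with an estimated correlation), but in triploids alone 5 of 14 were higher and 5 lower. Of 63 respiratory chain genes 38 were lower and 2 higher (camera adjusted p = 1.9e-08, adjusted p = 0.705 with an estimated correlation), while in triploids alone, with the marker differences above, 40 were higher and 1 lower. Of the detoxification genes 44 were higher and 10 lower, and in triploids alone 54 of 66 were higher and 5 lower. The test called 7612 genes, 5567 higher and 2045 lower, and in triploids alone 8064, 4308 higher and 3756 lower. The share higher was 73.1%, against 52.1% on TPM, 61.9% by DESeq2 and 62.9% with RLE scaling, which moved the median of all genes by −0.355, −0.213 and −0.18.

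In F3 male abdomens, some cuticle and royal jelly-like genes were higher and some P450 genes lower in diploids than in haploids. Mrjpl3 rose by 2.30 ± 0.33 (321 against 65.3 CPM, adjusted p = 0.00031, n = 5 and 5), CPR35 by 2.23 ± 0.32 (adjusted p = 0.00036), CPR37 by 2.22 ± 0.57 and nAChRa1 by 1.15 ± 0.29. CYP6AQ4 fell by 1.57 (SE 0.26, 885 against 2630 CPM, adjusted p = 0.00075), CYP9AG4 by 1.48 (SE 0.25), the carboxylesterase gene CCE-A6 by 1.87 (SE 0.21) and Zasp66 by 0.93 (SE 0.20), and CYP6CK10 was at 0.288 against 5.40 CPM, whereas the P450 gene CYP4G43 rose by 1.04 ± 0.28 (adjusted p = 0.0151). Tra fell by 0.70 (SE 0.14, 31.5 against 51.0 CPM, adjusted p = 0.0026), and Dsx (−0.13 ± 0.15, adjusted p = 0.61) and Fru (−0.29 ± 0.21, adjusted p = 0.38) were not called. Of 69 detoxification genes 16 were lower and 5 higher, or 21 and 6 adjusted over the list alone (camera adjusted p = 0.00153, adjusted p = 0.167 with an estimated correlation). Of 16 neuronal genes 3 were higher and 1 lower, or 4 and 1 adjusted over the list alone, and of 13 yellow and royal jelly-like genes 3 were higher and 1 lower (camera adjusted p = 0.0154 for both, adjusted p = 0.167 with an estimated correlation for both). The test called 1882 of 11358 genes, 912 higher and 970 lower. On TPM 64.2% of calls were higher in place of 48.5%.

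In F15 male abdomens, part of the respiratory chain genes were called higher in diploids than in haploids. Of 65 such genes 26 were higher and 0 lower, or 46 and 0 adjusted over the list alone (camera adjusted p = 1.77e-13, adjusted p = 0.556 with an estimated correlation), and 19 were higher and 0 lower on TPM. Uqcrc2 rose by 0.96 ± 0.18 (adjusted p = 0.0042, n = 5 and 5), Ndufa10 by 0.66 ± 0.14 and Atp5o by 1.00 ± 0.22. The diploid library D119 held head markers (Lop1 at 334.8 CPM, Pdf at 8.395 and ACP at 10.97), and without D119 those 3 genes were at 0.86, 0.57 and 0.89. CYP4AB9 rose by 3.09 ± 0.45 (261 against 30.6 CPM, adjusted p = 0.0034), CYP4AB12 by 2.37 ± 0.43 and the yellow gene Y-x1c by 2.81 ± 0.49. Of 69 detoxification genes 6 were higher and 0 lower, the same adjusted over the list alone (camera adjusted p = 0.0151, adjusted p = 0.556 with an estimated correlation). Tra (−0.18 ± 0.14, adjusted p = 0.39), Dsx (−0.30 ± 0.15, adjusted p = 0.19) and Fru (−0.47 ± 0.21, adjusted p = 0.14) were not called, although Dsx was without D117 (−0.46, adjusted p = 0.019) and Fru on TPM (adjusted p = 0.047). The test called 1259 genes, 889 higher and 370 lower, with 3509 at an unadjusted p under 0.05 and 2007 called by DESeq2. With the 2 F15 groups fitted alone it called 0, with 2727 at an unadjusted p under 0.05 and CYP4AB9 and Uqcrc2 at adjusted p = 0.069, and limma-trend on TPM called 554 higher and 892 lower. Single libraries moved the count: 480 without D120, 546 without D108, 573 without D109, 648 without D119, 698 without D118, 738 without D110, 1920 without D116 and 3025 without D117.

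The interaction in male abdomens was positive for CYP6CK10 (5.41 ± 0.61, adjusted p = 2e-04, n = 5 in each of 4 groups), CYP6AQ4 (2.21 ± 0.36), Uqcrc2 (1.21 ± 0.25) and Zasp66 (1.04 ± 0.27, adjusted p = 0.093 with female abdomens in the fit), and negative for CPR35 (−3.14 ± 0.45) and Mrjpl3 (−2.70 ± 0.45). Of 69 detoxification genes 16 were positive and 0 negative, or 22 and 2 adjusted over the list alone (camera adjusted p = 1.17e-06, adjusted p = 0.0823 with an estimated correlation). Of 65 respiratory chain genes 10 were positive and 0 negative, or 28 and 0 adjusted over the list alone (camera adjusted p = 5.6e-11, adjusted p = 0.558 with an estimated correlation). The contrast called 1184 genes, 680 positive and 504 negative, and 760 without D118, 775 without D108, 778 without D7 or D110 and 2015 without D117. On TPM 27.6% of calls were positive in place of 57.4%, with the median of all genes moved by −0.115. Both generations shared 64 higher genes, against 71.4 expected (one-sided Fisher's exact p = 0.84), and 43 lower genes, against 31.6 expected (p = 0.023). Across genes, which are not independent replicates, their fold changes had r = 0.133 and rho = 0.151.

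Averaged over ploidy, detoxification genes were more often higher and cuticle genes more often lower in male abdomens at F15 than at F3. CYP6AQ4 rose by 1.78 ± 0.18 (5370 against 1760 CPM, adjusted p = 1.8e-06, n = 10 and 10), CYP6CK7 by 1.53 ± 0.17, CYP9AG4 by 1.44 ± 0.18 and Cox15 by 1.08 ± 0.10. Cpap3-b fell by 1.74 (SE 0.21), CYP4AB21 by 2.68 (SE 0.31), CYP4AB12 by 2.42 (SE 0.30), Mrjpl8 by 1.87 (SE 0.23), Syt1 by 0.77 (SE 0.11) and Atp5d by 0.72 (SE 0.12). Of 69 detoxification genes 33 were higher and 8 lower, or 35 and 9 adjusted over the list alone (camera adjusted p = 0.00235, adjusted p = 0.159 with an estimated correlation). Of 25 cuticle genes 13 were lower and 1 higher, the same adjusted over the list alone (camera adjusted p = 0.00331, adjusted p = 0.159 with an estimated correlation). Of 16 neuronal genes 10 were lower and 1 higher (camera adjusted p = 0.00702, adjusted p = 0.157 with an estimated correlation). The test called 5206 genes, 2760 higher and 2446 lower. On TPM 32.6% of calls were higher in place of 53%, with the median of all genes moved by −0.122.

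Female and male abdomens differed in germline, cell cycle and detoxification genes. At equal ploidy oskar was at 309 CPM in females and 1.68 in males (5.60 ± 0.47, adjusted p = 9e-13, n = 10 and 10), Cdk1 at 79.5 against 1.15, the segmentation gene Kr at 17.1 against 0.411 and the potassium channel gene Slo at 140 against 16.9. Tra rose by 2.12 ± 0.10 (171 against 36.7 CPM, adjusted p = 1.3e-18), or 1.66 ± 0.14 without the libraries labelled F2 diploid female abdomen. All values and counts given here without those libraries compare F14 diploid females with F15 males alone. F3 males are therefore left out of that contrast too, and the effects of both omissions were not separated. Dsx was at 240 CPM in females and 415 in males (−0.85 ± 0.15, and −1.02 ± 0.21 without those libraries), but on TPM it was at −0.12 and not called (adjusted p = 0.35). SPH103 was at 7.42 against 2980 CPM, GstT2 at 65.1 against 1450 (−4.44 ± 0.20), CPR18 at 13.6 against 252 and Akhr at 11.8 against 167. Fru rose by 1.56 ± 0.15, or by 0.77 ± 0.21 (adjusted p = 0.0018) without those libraries. Also without them, oskar was at 8.71 ± 0.59, Cdk1 at 7.40 ± 0.51, Kr at 6.18 ± 0.67, Slo at 1.92 ± 0.29, SPH103 at −8.45 ± 0.80, GstT2 at −6.20 ± 0.33, CPR18 at −7.00 ± 0.45 and Akhr at −4.88 ± 0.32. Against haploid males Tra was 1.69 ± 0.10 higher and Dsx at −1.06 ± 0.15 (1.5 ± 0.14 and −1.29 ± 0.21 without the libraries in doubt), while Fru was 1.19 ± 0.14 higher but, again without them, at 0.33 ± 0.21 and not called (adjusted p = 0.16); CYP6AQ4 was at 62.8 against 3740 CPM (−7.55 ± 0.45 without them). Of 72 detoxification genes 54 were lower and 6 higher in females at equal ploidy, or 55 and 6 adjusted over the list alone (camera adjusted p = 2.42e-09, adjusted p = 0.0452 with an estimated correlation), and 56 and 8 without the libraries in doubt. Of 8 cell cycle genes 8 were higher (camera adjusted p = 0.0267, adjusted p = 0.536 with an estimated correlation), and of 47 serine protease genes 27 were lower and 11 higher (camera adjusted p = 0.0376, adjusted p = 0.536 with an estimated correlation). Of 65 respiratory chain genes 31 were higher and 7 lower, but 9 and 24 when F14 diploid females were compared with F15 diploid males alone. The equal-ploidy test called 9512 of 12265 genes, 4968 higher and 4544 lower, or 4929 and 4729 without those libraries. Against haploid males 9689 were called, 5212 higher and 4477 lower, or 5033 and 4395. On TPM 63.6% and 64.3% of calls were higher in place of 52.2% and 53.8%, with medians moved by 0.27 and 0.25; DESeq2 moved them by −0.18 and −0.192 and RLE scaling by −0.101 and −0.113.

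Heads and abdomens differed in most genes of both sexes. In females Syt1 was 4.39 ± 0.17 higher in heads (adjusted p = 9.2e-23, n = 20 and 19) and Tra 2.15 ± 0.14 higher (542 against 133 CPM), while oskar was at 11.4 against 492 CPM, Cdk1 at 1.36 against 172 and GstS8 at 14.8 against 347. The contrast without the libraries in doubt also left out the F2 diploid heads. It kept the F2 triploid abdomens, which differed from F14 female abdomens in markers of several tissues. In that contrast Syt1 was at 5.71 ± 0.22, Tra at 2.92 ± 0.18, oskar at −6.17 ± 0.37, Cdk1 at −7.60 ± 0.34 and GstS8 at −4.84 ± 0.19. In males Tra was 0.76 ± 0.09 higher in heads (73.3 against 43.6 CPM, n = 20 and 20) and Dsx lower (132 against 449 CPM, −1.77 ± 0.07, adjusted p = 8.2e-24), the receptor genes nAChRa11 and LCCH3 were at 74.5 and 142 CPM against 4.72 and 11.6, and CYP4G44, CYP6CK7 and Cht5 (chitinase) at 4.31, 4.39 and 11.5 CPM against 792, 217 and 440. Of 15 neuronal genes 15 were higher in female heads (camera adjusted p = 7.24e-07, adjusted p = 0.129 with an estimated correlation), and of 16 in males 14 were higher and 1 lower (camera adjusted p = 2.54e-05, adjusted p = 0.0137 with an estimated correlation). Of 5 neuropeptide and hormone genes 5 were higher in female heads (camera adjusted p = 0.00537, adjusted p = 0.0527 with an estimated correlation), and of 179 chemoreceptor genes 162 were higher and 1 lower (camera adjusted p = 0.000675, adjusted p = 0.677 with an estimated correlation). Of 71 detoxification genes in males 55 were lower in heads and 13 higher, or 55 and 14 adjusted over the list alone (camera adjusted p = 7.1e-06, adjusted p = 0.321 with an estimated correlation). In females 8 of 8 cell cycle genes and 9 DNA damage response genes were lower in heads (camera adjusted p = 0.000675 and 0.00537, adjusted p = 0.169 and 0.254 with an estimated correlation). The tests called 10151 of 12036 genes in females, 5383 higher and 4768 lower in heads, or 5477 and 4871 without the libraries in doubt, and 9875 of 11981 in males, 4816 higher and 5059 lower. On TPM 69.1% of the male calls were higher in place of 48.8%, with the median of all genes moved by 0.475, and in females DESeq2 and RLE scaling moved it by 0.275 and 0.138.

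**Figure D3:**
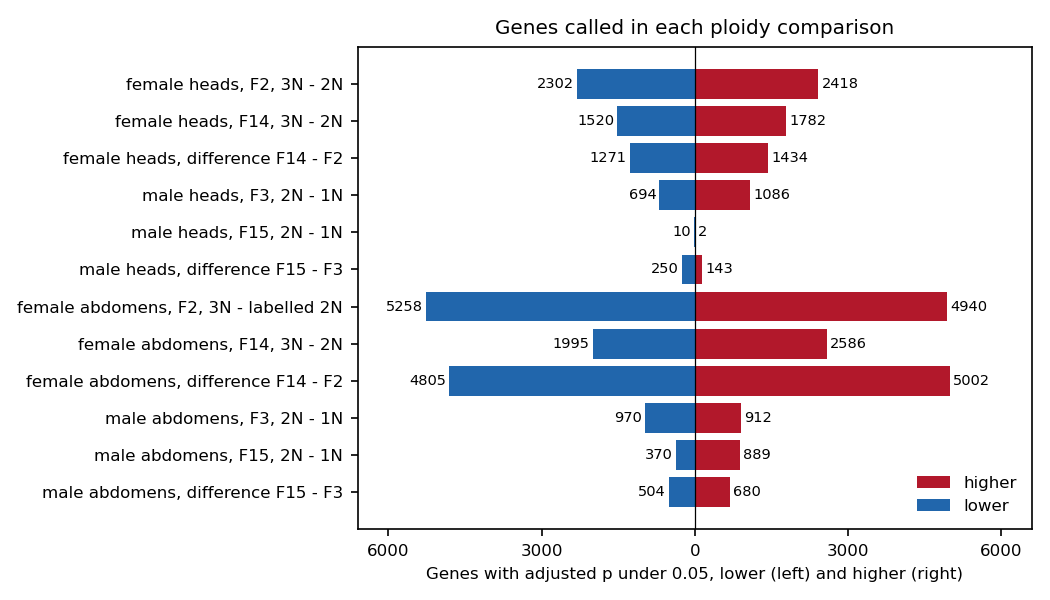
Number of genes called at an adjusted p under 0.05 by edgeR (x axis) in each of 12 contrasts (y axis), 8 between ploidies and 4 of ploidy by generation. Bars to the right count genes higher with the added chromosome set, or positive in a ploidy-by-generation contrast, and bars to the left those lower or negative. F15 male heads have 2 and 10 calls and F2 female heads 2418 and 2302.

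Ploidy calls were shared between tissues in F14 females and F3 males. In F14 females 912 genes were higher in triploid heads and abdomens alike, against 410 expected (2.23 times). Another 519 were lower in both, against 270 expected. Tm1, Zasp66 and CYP4AB9 were higher in both tissues. The triploid abdomen libraries D86 and D87 held more of the head genes (2.49 and 2.11 log2) than D89 and D90A (0.66 and 0.98). Whether that added shared genes was not tested, and the F14 overlap was not repeated without D86 and D87. In F3 males 295 were higher in both tissues, against 86.3 expected (3.42 times), and 219 lower, against 58.4 expected, among them Tra, CYP6AQ4 (lower) and Mrjpl3 and CPR35 (higher). The F3 head calls came from the edgeR fit that also held the F15 heads. With the F3 head groups fitted alone, edgeR called neither Tra (adjusted p = 0.14) nor Mrjpl3 (adjusted p = 0.06) in heads. The overlap was not repeated with that fit. In F15 males 1 gene was shared in each direction. Between the sexes 282 genes were higher with the added set in F14 female and F15 male abdomens, against 165 expected (1.71 times, one-sided Fisher's exact p = 1.7e-24), and 291 in F2 female and F3 male heads, against 239 expected (1.22 times, p = 4.3e-05). The F15 male abdomen calls came from the fit that also held the F3 abdomens, and no gene was called without those. Their number of 1259 ran from 480 to 3025 without single libraries. Overlaps between the sexes were not repeated with other fits. Lower genes were shared less clearly, with 76 in the abdomens against 67.3 expected (one-sided Fisher's exact p = 0.13) and 148 in the heads against 143 expected (p = 0.32), and F14 female and F15 male heads shared 1 higher and 2 lower genes (p = 0.3 and 0.41). Across genes, which are not independent replicates, fold changes in both tissues had r = 0.379 and rho = 0.353 in F14 females, and r = 0.333 and rho = 0.369 in F3 males.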

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

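Tests chosen only after the results were seen were those of heads in place of abdomens, of a label exchange with F2 heads, of abdomens mixed with heads and of muscle share, and the fits without named libraries or with thinned counts.

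In the libraries labelled F2 diploid female abdomen the opsin Lop1 and the synaptic gene Syt1 were at head levels and oskar was low. An exchange with the F2 diploid heads is argued against by those heads, whose abdomen genes lay 0.23 above F14 diploid heads (log2 median). Abdomen genes lay at −4.33 from F14 diploid abdomens, which argues against abdomens with a minor share of heads. Heads with a small share of abdomen cannot be told apart by this level. In D26 the abdomen genes had a log2 median of 1.96. That median ran from −0.31 to 0.45 in D27 to D30 and from −0.26 to 1.24 in F2 diploid heads. Entry of 1 set of head libraries under both labels is argued against by a lowest chi-square per degree of freedom of 74.1 over 25 pairs. Abdomen genes differed from F2 diploid heads by a median of 0.04, so heads in all 5 libraries remain a candidate explanation. A biological difference of F2 diploid abdomens had no test of its own. The 1260 genes chosen as head genes in F14 diploid females lay at a median log2 of −0.07 (quartiles −0.42 and 0.13) from F2 diploid heads. They lay at 4.49 (quartiles 3.51 and 5.51) from F14 diploid abdomens, which argues against abdomens with a biological difference in these 5 libraries. All results that use these libraries rest on this point.

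In female heads the triploid effect differed between F2 and F14 for 2705 genes, with the cuticle genes CPR37 at 11.24, CPR48 at 9.33 and apd-3 at 17, the muscle genes Tm1 at 5.43 and Zasp66 at 4.73, CYP4AB14 at 6.41, Def1-2 at 6.14, Atp5b at 3.39, nAChRa10 at 2.21, Pdf at −2.30, Rpl41 at −3.04 and SP128 at −5.27 (log2 differences). Exchanged ploidy labels in 1 generation would give opposite fold changes, but their correlation across genes was 0.158 and more calls were alike than opposite. Without D31 and D32 the number was 3058, and after thinning it was 2614, which argues against those libraries and against depth as the whole cause. A different share of muscle in the heads cannot be told apart: Tm1 and Tm2 differed by 8.21 combined standard errors, but Tm2 was nearly uniform between groups and so may not mark the same muscle. Culture and generation remain open as untested. Other splits called fewer genes (real 2705, highest of the other splits 0, 100 drawn), but they exchanged ploidy labels within each generation. They therefore cannot show how many interaction calls an equal ploidy effect in both generations would give.

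The ploidy contrast called 1780 genes in F3 male heads and 12 in F15 male heads, or 378 and 128 with each generation fitted alone, so the size of the gap depended on the fit, and 393 genes carried an interaction, with CYP6AQ4 at 2.18, CYP6CK11 at 1.35, Creb at 0.92, CYP4AB15 at −3.10, Mrjpl3 at −2.68, CPR35 at −2.26, Cctgamma at −1.03 and Or140 at −2.37. The calls of CYP6CK11 (adjusted p up to 0.088) and CYP4AB15 (up to 0.063) were lost without single libraries, among them D101, D103, D105, D112, D113, D115, D1A and D5 for both. Without D13 the F3 count was 1962, so that library is not its source. After thinning the F15 count was 8. Thinning only removes counts, so this cannot show whether depth held the F15 number down. Median depths of haploid and diploid heads were 18 and 20.2 M at F15, against 19.1 and 18.3 M at F3. The common dispersion of F15 heads fitted alone was 0.0487, below 0.137 at F3, which argues against a wider spread at F15, but the fit behind 1780 and 12 pooled both. A change in the line between generations may contribute but was not tested, and generation is confounded with everything else that differed between F3 and F15 cultures.

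Other differences between generations in the ploidy effect came from abdomens. In female abdomens 9807 genes differed, with cycB at −9.22, Cdk1 at −8.45 and nanos at −8.41, all resting on the libraries labelled F2 diploid female abdomen. In male abdomens 1184 genes differed, with CYP6CK10 at 5.41, CPR35 at −3.14, Mrjpl3 at −2.70, CYP6AQ4 at 2.21, Uqcrc2 at 1.21 and Zasp66 at 1.04.

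Single libraries stood far from the rest of their group in 17 of 128 groups and measures tested. Chance would give about 1 in 20 if values were normally distributed. The values were untransformed totals and CPM, so that rate need not hold. Total counts were 45.8 M in D93 (others 16.2 to 17.7 M) and 36.4 M in D116 (others 22.7 to 24.9 M). Tra was at 100.9 CPM in D13 (others 44.7 to 53.6). Dsx was at 374 CPM in D22 (others 253 to 286), at 96.8 in D1 (others 126 to 138) and at 84 in D81 (others 165 to 189). Fru was at 74 CPM in D6 (others 39.8 to 44.4). Lop1 was at 4683 CPM in D26 (others 1980 to 2640), at 6.39 in D38 (others 0.175 to 0.664) and at 335 in D119 (others 0.414 to 16.1). For oskar the level was 39.6 CPM in D26 (others 2.75 to 6.33), 33.5 in D24 (others 2.1 to 10), 5.68 in D1 (others 2.72 to 3.18), 8.96 in D95 (others 3.64 to 5.12) and 15.3 in D108 (others 1.68 to 3.18). Zasp66 was at 730 CPM in D28 (others 334 to 446) and at 5.89 in D40 (others 1.66 to 2.58).

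For each of the 22 contrasts the real split called more genes than every other split drawn (1 split of the drawn ones reached the real count, the real one itself). The margins were small in some. Other splits mix the real groups, which widens the spread within groups, so low counts in them were partly built in. For the interactions, splits exchanged ploidy labels within each generation and so did not test an equal ploidy effect in both. The splits alone therefore do not exclude chance. In male abdomens at F15 there were 1259 genes against 1188 in the highest other split, with 0 when the 2 groups were fitted alone and 480 without D120, and in the interaction 1184 against 906. The 12 genes of F15 male heads fell to 1 without D115. Real and highest other counts were 4720 and 0 in F2 female heads, 3302 and 6 in F14 female heads, 1177 and 226 between generations of female heads, 1780 and 1.1e+02 (rounded) in F3 male heads, 12 and 3 in F15 male heads, 393 and 32 for the interaction in male heads and 2621 and 0 between generations of male heads. In abdomens they were 10198 and 3 in F2 females, 4581 and 1 in F14 females, 9807 and 0 for the interaction in females, 7612 and 1645 between generations of females, 1882 and 14 in F3 males and 5206 and 6 between generations of males. For sex (50 splits) they were 2838 and 1 and 2446 and 2 in heads, and 9512 and 3435 and 9689 and 3115 in abdomens. For tissue (40 splits) they were 10151 and 41 in females and 9875 and 4653 in males.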

How the results depend on the processing

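Fits chosen after the data were seen were those with thinned counts, without D31 and D32, without D86 and D87, without D13 and without the libraries labelled F2 diploid female abdomen; the tests by DESeq2, RLE scaling, no filter, TPM, other libraries in the fit and without libraries named A or B were planned. Of 260 named gene values, 214 kept direction and side of the threshold in every alternative and without every single library.

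Genes called moved by over 1.5 times as follows, and the cause was not tested except where fewer libraries or genes enter by construction. DESeq2 gave 1809 between generations of female heads, 53 higher and 53 lower (1.1e+02 in all) in F15 male heads, 896 for the interaction in male heads, 2007 in F15 male abdomens and 1929 for the interaction in male abdomens. On TPM F3 male heads gave 960 and the male head interaction 216. Without libraries named A or B, which leaves fewer libraries, the numbers were 759 between generations of female heads, 1155 in F3 male heads and 244 for the male head interaction. With other libraries in the fit they were 1926 between generations of female heads, 378 in F3 and 128 in F15 male heads, 135 for the male head interaction, 4756 for diploid females against haploid males in heads, and 0 in F15 male abdomens (2727 at an unadjusted p under 0.05 in edgeR, 2007 by DESeq2 and 1446 on TPM with all 4 groups). Without D31 and D32 female heads between generations gave 2740, and without D86 and D87 F14 female abdomens gave 2776.

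Overlaps of both generations by DESeq2 were 10 higher and 16 lower genes in male heads, and 1.2e+02 higher and 1.1e+02 lower (rounded) in male abdomens; without a filter 27 lower were shared in male abdomens. Of the 86 list calls, 3 held with an estimated correlation, where the members' own correlation widens the test by construction.

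Directions turned for values that passed no threshold: Dsx 0.05 and Fru −0.08 in F2 female heads without D31 and D32, Pdf −0.30 and Fru −0.18 in F14 female heads on TPM, and Fru 0.03 in F15 male heads on TPM. The cause was not tested.

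Without 1 library at a time the counts ran from 758 (without D94) to 1499 between generations of female heads, from 1053 (D5) to 1965 in F3 male heads, from 1 (D115) to 22 (D112) in F15 male heads, from 225 (D101) to 865 (D13) for the male head interaction, from 480 (D120) to 3025 (D117) in F15 male abdomens and from 760 (D118) to 2015 (D117) for the male abdomen interaction. Fru ran from −0.21 to 0.15 in F3 and from −0.21 to 0.09 in F15 male heads. The other counts stayed within 1.5 times.

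Small effects were often missed in simulation: at a 1.5-fold change edgeR recovered 8.96% of simulated changes in F2 female heads and 17.9% in F3 male heads, and at 4-fold 72.7% and 89.4%. No paired analysis was possible because library names are unique and the labels pair no libraries.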

Other observations

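None of the tests in this part was chosen after its result was seen.

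CYP4G43, of the P450 family that makes cuticular hydrocarbons, had a mean of 9700 ± 3470 CPM (SD, n = 5) in F3 haploid, 19800 ± 4780 in F3 diploid, 14100 ± 3590 in F15 haploid and 12800 ± 3870 in F15 diploid male abdomens. In female abdomens it was at 450 ± 40.9 CPM in F2 triploids, 1410 ± 357 in F14 diploids and 2150 ± 1030 in F14 triploids (n = 4). The libraries labelled F2 diploid female abdomen are left out here. F2 triploid abdomens also differed from F14 female abdomens in markers of several tissues, such as Syt1 (2.975 to 4.303 against 18.36 to 101.5 CPM). Whether tissue shares set the levels of CYP4G43 and C1q-VP in F2 triploid abdomens was not tested. With ploidy, edgeR called CYP4G43 higher in abdomens of F3 diploid males (1.04 ± 0.28, adjusted p = 0.0151) but not in F15 males or F14 females. The venom protein gene C1q-VP was at 1.83 ± 0.884 CPM in F2 triploid female abdomens, at 25.7 ± 4.37 in F14 diploid and 44.7 ± 14.9 in F14 triploid female abdomens (log2 fold change 1 ± 0.25, adjusted p = 0.0048), and at means from 296 to 367 CPM in the 4 groups of male abdomens. Among the F14 triploids, D86 and D87, which stood apart, were at 48.08 and 63.52 CPM. D89 and D90A were at 38.87 and 28.46, against 21.82 to 33.14 CPM in F14 diploids.

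A hypothesis of whole blocks of the genome shifted with ploidy, as the gain of single chromosomes might give, was tested on blocks of 100 neighbouring genes in F14 female heads. The SD of the block medians of triploid against diploid fold changes was 1.23 times the mean of shuffled gene orders, under the limit of 2 set for such a shift, and the SD of 0.1 was within the 1000 shuffles (highest 0.102). In the other ploidy comparisons the ratio ran from 1.1 to 1.87, also under the limit. The SD exceeded every shuffle in F2 female heads (0.14 against 0.127), F14 female abdomens (0.163 against 0.124), F15 male abdomens (0.0663 against 0.0637) and F2 female abdomens (0.849 against 0.554), the last of which rests on the libraries in doubt. Some clustering of fold changes among neighbouring genes was therefore present in these 4, and its cause was not tested.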
